A study of Rattus norvegicus with 9 samples.

How the data were processed

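Gene expression was measured on 9 Illumina arrays from rats, 3 at each of 5, 14 and 28 days post lesion (dpl). Per the labels, demyelination was induced with 0.1% ethidium bromide in the caudal cerebellar peduncle, a white matter tract, of Sprague Dawley rats aged 12 weeks, and the lesions were cut out by laser capture. Ethidium bromide kills oligodendrocytes and astrocytes locally, and the lesion then remyelinates. Per the labels' protocols, biotinylated cRNA was prepared with the Ambion TotalPrep kit. The 3 arrays of a time point are biological replicates per the series' design text. Whether each came from its own animal is not given in the sources used here, so p-values measure the spread between these samples.

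Both kinds of table were used. The raw table holds, per the file headers, the average bead signal intensity of 22226 targets on a linear scale, with a detection p-value for each target and array; the authors applied no normalization to it, per the file headers. The authors' normalized table holds 10552 probes. Its deposited values lie on a log2 scale: each array holds the same set of values, as quantile normalization gives, the values are not centred by gene, and the column medians are all 8.31. The transform and filter behind it are not given in the sources used here. Set against the sorted raw log2 signals, its slope was 0.52 at a raw log2 signal of 6.5 and 0.96 at 10, so differences of dim genes are understated. The number of raw targets with a detection p of at most 0.01 on at least 1 array was also 10552. The slope, and the background estimated below, take these targets and the table's probes to be the same set. That could not be checked.

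The tables share 0 identifiers, and rows were not matched by their values. Raw columns name the time point and not the replicate number. Counts of targets were therefore taken from the raw table as fixed beforehand, and gene names, gene lists and values per gene from the authors' normalized table. The platform annotation names 7679 of its probes, each with 1 symbol (0 with several), and leaves 2873 unnamed here. These make 7574 genes, 103 of them with several probes, represented by the brightest. The RefSeq table, of assembly GRCr8, holds 7670 of the platform's gene identifiers and updated 21 list symbols. The array's genome build is not given in the sources used here, and no coordinates are printed.

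Raw signals were processed with neqc in limma 3.58.1 under R 4.3.3 (background from the detection p-values, offset 16, quantile normalization, log2). Targets with a detection p under 0.01 on at least 3 of the 9 arrays were kept, 9404 in all. Each time point had its own mean in lmFit, eBayes gave moderated tests for the 3 pairwise contrasts, for 14 dpl against the mean of the other time points and for any difference, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The same fit was used on the authors' normalized table. The 23 gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 69 tests. The tests, the lists and the rule for named genes were fixed before the data were examined, for values from neqc. Taking genes and lists from the authors' normalized table, and using the estimated background below in place of detection p-values in that rule, were choices made after the data had been seen.

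The background that neqc estimated is doubtful. Its mean was 101 to 129 and its SD 361 to 482 on the 9 arrays, above the median signals of 79.6 to 94.1, because some bright targets carry a detection p above 0. After this had been seen, 3 definitions of such targets were tried in turn, with the counts of called targets seen under each. They left 180, 196 and 207 targets out of the background estimate. The latter definitions gave background means of 63.9 to 75.7 and more called targets. Since they were chosen after the data and the counts had been seen, neqc as fixed beforehand stayed the main setting, and all 3 are given as alternatives.

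Named genes are, for each pairwise comparison, the 8 highest and 8 lowest by log2 difference among genes past the threshold whose arrays do not overlap and that were above background at the brighter time point, up to 4 members of each list with the smallest p, and a fixed set of retinoid receptors and cell type markers. For 14 dpl against the mean of the others, 5 per direction were taken. Because the normalized table has no detection p-values, background on it was estimated from the number of undetected raw targets, at 7.26 to 7.29. A gene below it on all arrays of a time point has only a bound there, given as "at least".

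Detected targets numbered 8465 to 9191 per array, 38.1% to 41.4% of all, and the number of arrays limits the precision. Arrays were simulated with the means and limma's moderated spreads of the raw table for 28 against 5 dpl. Of 100 targets changed by 1 (log2) 96% were recovered, and of 100 changed by 0.5, 80%. There were 9 false calls among the unchanged targets of the 9404. On the authors' table these shares were 93% and 66%, with 5 false calls among the unchanged probes of the 10552. The real contrast called 43.9% of the raw targets, far more than were changed here, so the recovered shares need not hold for it. The simulated genes varied independently, and camera then called both tests of a shifted list and 1 of 67 others.

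Alternatives covered the background correction, the normalization, the filter, the source of the values, the variance model, array weights, a replicate block, fits of only the time points compared, each array left out, the mean of a gene's probes and an estimated inter-gene correlation. A slide block was not run, since no slide is named.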

Results

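The experiment followed gene expression in demyelinated lesions of the rat caudal cerebellar peduncle at 5, 14 and 28 days post lesion (dpl), with 3 arrays per time point. It addresses which genes change as a lesion remyelinates, with the retinoid X receptors in view. Median raw signals were 87.9 to 94.1 at 5 dpl, 79.6 to 84.0 at 14 dpl and 86.5 to 91.4 at 28 dpl. Differences are log2 differences of the authors' normalized values with the standard error (SE) of the limma fit, n = 3 arrays per time point, and adjusted p-values are limma's with Benjamini-Hochberg adjustment. Of the 9404 targets of the raw table, 3648 differed among the time points, as did 4365 of the 10552 probes of the authors' normalized table. One array stood apart within its group: 5 dpl replicate 1 lay at -23.74 on the first principal component (70.1% of the variance), against -37.70 for both other 5 dpl arrays. Its neuron list score was 1.23 (log2, relative to the mean of all arrays), against -0.42 and -0.18 on the others. The myelin score of that array was -1.03, against -1.53 and -1.44. Where 0 genes of a list are given beside calls in the other direction, limma also gave 0 at an unadjusted p under 0.05, unless a number is given. Ranges of an adjusted p are over the alternative settings run for that result.

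From 5 to 14 dpl, genes of myelin and mature oligodendrocytes rose. Of 24 measured members 20 rose and 0 fell (21 and 0 adjusted over the list alone), among them Mog by 3.20 (SE 0.28), Mal by 3.55 (SE 0.32), Mobp by 3.23 (SE 0.20) and Mbp, myelin basic protein, by 1.79 (SE 0.14). The list's camera test gave an adjusted p = 4.07e-16 with the preset correlation and an adjusted p = 0.313 with an estimated correlation. Genes typical of Schwann cells, the myelinating cells of peripheral nerve, rose in 6 of 7 cases (6 adjusted over the list alone), with Pmp22 up by 3.09 (SE 0.21), Dhh by 2.90 (SE 0.21) and Scn7a by 3.23 (SE 0.34). The test gave an adjusted p = 1.24e-06, and an adjusted p = 0.259 with an estimated correlation. Sostdc1, a secreted BMP antagonist, had the largest rise among the named genes, 3.98 (SE 0.47, adjusted p = 0.000772).

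Rxrg, which encodes retinoid X receptor gamma, rose from 8.18 at 5 dpl to 11.53 at 14 dpl, a difference of 3.35 (SE 0.24, adjusted p = 0.000151) or 10.2-fold. Rxrb rose by 0.32 (SE 0.07, adjusted p = 0.0128). Rxra, Rara and Rarb did not pass the test, with differences of -0.10, 0.03 and 0.13. In the list of retinoid receptors, their partners and retinoid metabolism 5 of 18 members rose and 1 fell (5 and 1 adjusted over the list alone), with an adjusted p = 0.335 for the list. Those that rose numbered 2 without 5 dpl replicate 2 or 14 dpl replicate 2 or 3, and 3 without 5 dpl replicate 3 or 14 dpl replicate 1, with only these time points fitted, or among the 12 members above the estimated background on all 9 arrays. The member that fell was Nr1h3, a liver X receptor, by 1.46 (SE 0.17).

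Astrocyte genes rose in 8 of 14 cases (12 adjusted over the list alone) from 5 to 14 dpl, including Gfap by 1.94 (SE 0.15) and S100b by 1.83 (SE 0.20), with an adjusted p = 7.23e-07, and an adjusted p = 0.371 with an estimated correlation. The astrocyte score of 5 dpl replicate 1, the array high in neuron genes, was -0.33 against -1.24 and -1.18. Which cells carried the genes of the oligodendrocyte progenitor list was not tested. Of its 11 measured members 5 rose and 4 fell (6 and 4 adjusted over the list alone). Those that fell numbered 1 without 5 dpl replicate 1 or 3, 14 dpl replicate 1 or 2 or 28 dpl replicate 1, and 2 without 5 dpl replicate 2 or 14 dpl replicate 3; cyclic loess or only these time points also gave 1. Sox10 rose by 0.81 (SE 0.15) and Vcan fell by 0.72 (SE 0.14), while Pdgfra differed by 0.48 (SE 0.16) with an adjusted p = 0.0635, which was 0.0245 without 14 dpl replicate 1, 0.0440 without 5 dpl replicate 2, 0.0437 with cyclic loess and 0.0211 with array weights (range 0.0211 to 0.194). Of 20 neuron genes 0 passed limma's test and 2 had an unadjusted p under 0.05, both lower at 14 dpl (0 adjusted over the list alone), and 1 passed, lower, without 5 dpl replicate 2 or 3. The list's adjusted p = 0.0243 toward lower values became 0.588 without 5 dpl replicate 1, 0.0586 without 14 dpl replicate 1 and 0.102 with only probes above the estimated background on all 9 arrays, and was an adjusted p = 0.698 with an estimated correlation (range 0.000161 to 0.698).

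Cytokine and chemokine genes fell from 5 to 14 dpl. Of 22 members 14 fell and 0 rose (16 and 0 adjusted over the list alone), among them Ptgs2, the inducible cyclooxygenase, which fell by 1.99 (SE 0.18), and Cxcl13, which fell by 2.88 (SE 0.46). The list had an adjusted p = 6.53e-07, and an adjusted p = 0.471 with an estimated correlation. The cytokine score of 5 dpl replicate 1 was 0.28, against 0.66 and 1.21 on the other 5 dpl arrays. Of 22 microglia and macrophage genes 7 fell and 0 rose (8 and 0 adjusted over the list alone; 1 higher at an unadjusted p under 0.05). Cd14 fell by 1.96 (SE 0.24) and Mrc1, the mannose receptor, fell by 1.34 (SE 0.11), while Aif1 differed by -0.09 (SE 0.09). The list did not pass, with an adjusted p = 0.0659, and passed without 14 dpl replicate 1 (0.0196) or without 28 dpl replicate 1 (0.0454), 2 (0.0261) or 3 (0.0486), and with cyclic loess (0.0246), with a range of 0.0196 to 0.643. Mmp7, a matrix metalloproteinase, fell by 3.79 (SE 0.39), Plac8 fell by 2.60 (SE 0.32) and Arg1, arginase, fell by 2.53 (SE 0.32). Genes of the endothelial cell and pericyte list fell in 5 of 9 cases (5 adjusted over the list alone), with Anpep down from 11.37 to 9.33. The list had an adjusted p = 0.00213, and an adjusted p = 0.259 with an estimated correlation. Those that fell numbered 3 without 5 dpl replicate 2 or 3 or 14 dpl replicate 2 or 3. Which cells carried Anpep was not tested. Of the raw targets, 799 were higher and 835 lower at 14 dpl, and of the authors' normalized probes 1131 were higher and 1062 lower. Which direction held more calls turned with the setting. The raw table gave 1155 higher and 1038 lower with no background correction, 1169 and 1040 with normexp on the signals alone, 1164 and 993 with definition 2 or 3 of a re-estimated background and 654 and 605 with only these time points. It gave 678 and 636 without 1 array of 14 dpl, and 807 and 785 or 726 and 703 without 1 of 28 dpl. The normalized probes numbered 1434 and 1564 with array weights and 1227 and 1352 without 5 dpl replicate 1. The raw arrays carry no replicate numbers; leaving out 1 of them gave 342 higher and 360 lower or 395 and 404 for 2 of the 14 dpl arrays, and 379 and 507 or 394 and 516 for 2 of the 5 dpl arrays. The normalized probes numbered 668 and 617 without 14 dpl replicate 2 and 727 and 643 without its replicate 3, and 706 were lower without 5 dpl replicate 3.

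**Figure D1:**
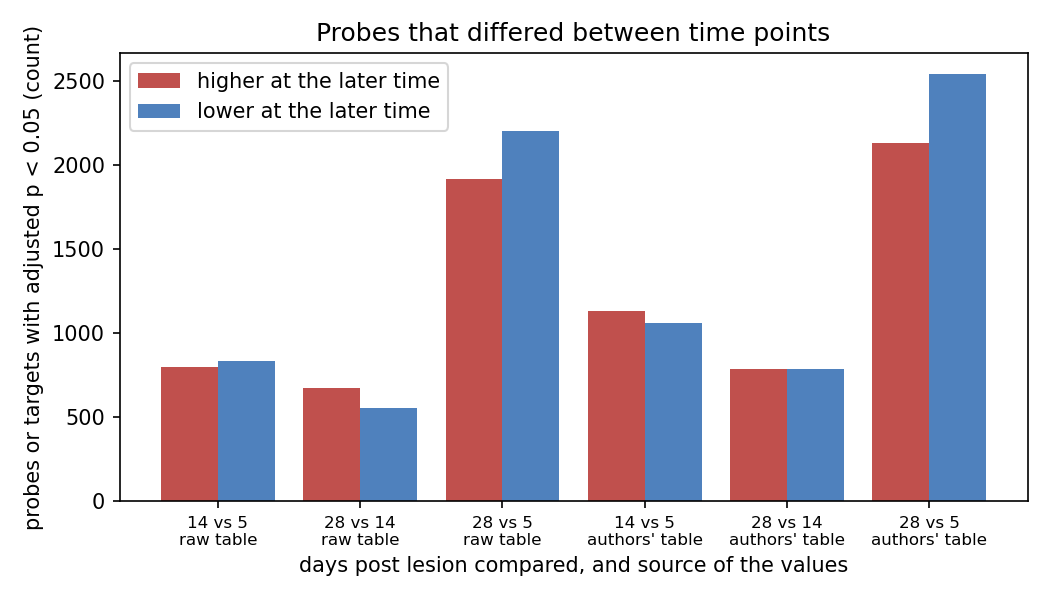
Bars give the number of targets of the raw table, or probes of the authors' normalized table, that were higher (red) or lower (blue) at the later of the time points compared (adjusted p under 0.05, limma, 3 arrays per time point). The largest bars belong to 28 against 5 dpl, with 1921 higher and 2205 lower targets in the raw table.

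From 14 to 28 dpl, cell cycle genes fell. Of 25 members 22 fell and 0 rose (24 and 0 adjusted over the list alone), among them the mitotic kinase Cdk1, which fell by 2.08 (SE 0.19), Kif11, which fell by 1.78 (SE 0.16), and Aurkb, which fell by 1.56 (SE 0.21). The list had an adjusted p = 4.48e-18, and an adjusted p = 0.329 with an estimated correlation. From 5 to 14 dpl, 2 of these genes fell, Mcm6 (a difference of -0.35) and Mcm2 (-0.29), and 0 rose with limma, where 4 were lower and 1 higher at an unadjusted p under 0.05 (0 and 0 adjusted over the list alone; adjusted p = 0.7 for the list). Without 5 dpl replicate 1, 5 fell, and with array weights 4 fell and 1 rose. With cyclic loess or either background filter, or without 14 dpl replicate 1 or 5 dpl replicate 2, 1 gene rose. Neither call held without 14 dpl replicate 1 (adjusted p of 0.0810 for Mcm6 and 0.0742 for Mcm2), 14 dpl replicate 2 (0.117 and 0.138), 5 dpl replicate 2 (0.0981 and 0.120) or 5 dpl replicate 3 (0.105 and 0.117). That of Mcm2 also ended without 14 dpl replicate 3 (0.0749), 28 dpl replicate 1 (0.0511) or 28 dpl replicate 2 (0.0554). Fitting only the time points compared gave 0.0548 for Mcm6 and 0.0698 for Mcm2, and the ranges were 0.0148 to 0.117 and 0.00712 to 0.138.

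Myelin genes rose further from 14 to 28 dpl, 17 of 24 (18 adjusted over the list alone; 11 without 28 dpl replicate 1 or 3), with Mog up by 1.71 (SE 0.28), Ermn by 2.15 (SE 0.25) and Car2 by 1.71 (SE 0.17). The adjusted p was 2.4e-11, and the adjusted p = 0.329 with an estimated correlation. Hapln2, a link protein of the node of Ranvier, had the largest rise among the named genes, 2.91 (SE 0.20, adjusted p = 0.000187). Cholesterol synthesis genes rose in 11 of 16 cases (13 adjusted over the list alone), including Sqle by 0.96 (SE 0.12) and Dhcr7 by 0.62 (SE 0.07), with an adjusted p = 5.65e-09, and an adjusted p = 0.259 with an estimated correlation. Of 14 astrocyte genes 3 rose (9 adjusted over the list alone; 9 without 5 dpl replicate 1, with only these time points or with array weights, when 1 fell, and 5 without 5 dpl replicate 2), with Gfap up by 0.95 (SE 0.15), S100b up from 11.04 to 12.55, an adjusted p = 0.000197, and an adjusted p = 0.5 with an estimated correlation.

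Rxrg was 11.06 at 28 dpl, a difference from 14 dpl of -0.47 (SE 0.24, adjusted p = 0.233) that did not pass the test. The Schwann cell list likewise had 0 of 7 members past the threshold with limma and 2 higher at an unadjusted p under 0.05 (0 adjusted over the list alone), and 1 was higher without 5 dpl replicate 1 or 28 dpl replicate 2, or with array weights. The list's adjusted p was 0.115, and 0.0471 without 14 dpl replicate 3 and 0.0453 without 28 dpl replicate 2 (range 0.0453 to 0.584). Pmp22 differed by 0.38 (SE 0.21). Aldh1a1, which makes retinoic acid, rose by 1.97 (SE 0.34, adjusted p = 0.0074). In its retinoid list 4 of 18 members rose and 0 fell (4 and 0 adjusted over the list alone). Only 1 rose without 14 dpl replicate 1 or 3 or 28 dpl replicate 1, and 2 without 14 dpl replicate 2, 28 dpl replicate 2 or 3 or 5 dpl replicate 3, or with cyclic loess. Of its 12 members above the estimated background on all 9 arrays 0 rose. The list had an adjusted p = 0.0705, and 0.0248 without 28 dpl replicate 3 and 0.0323 without 5 dpl replicate 1 (range 0.0248 to 0.555).

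Microglia and macrophage genes fell from 14 to 28 dpl in 12 of 22 cases (14 adjusted over the list alone), among them P2ry12 (a difference of -1.30, SE 0.12), Fcgr2b (-1.42, SE 0.17) and C1qb (-1.12, SE 0.18). The list had an adjusted p = 7.6e-07, and an adjusted p = 0.36 with an estimated correlation. Of 22 cytokine genes 1 fell, Il1a (a difference of -0.71, SE 0.20), and 0 did adjusted over the list alone (adjusted p = 0.677 for the list). The adjusted p of Il1a was 0.0491, and 0.160, 0.0530 and 0.109 without 14 dpl replicate 1, 2 and 3, 0.146 and 0.139 without 28 dpl replicate 1 and 3, and 0.0664 without 5 dpl replicate 2 (range 0.0152 to 0.160). Without 5 dpl replicate 1, 3 cytokine genes fell and 1 rose, and without 5 dpl replicate 3, 2 fell; array weights gave 3 that fell, and only these time points 2 that fell and 1 that rose. Of 11 members of the progenitor list 0 passed limma's test, with 2 higher at an unadjusted p under 0.05 (0 adjusted over the list alone). The list had an adjusted p = 0.677, upward, with a mean difference of 0.02 and a median below 0. Without 5 dpl replicate 1, 14 dpl replicate 3 or 28 dpl replicate 2, or with the trend or either background filter, 1 member rose. Sox10 and Olig1 both did with cyclic loess (adjusted p of 0.0381 and 0.0312) or array weights (0.0215 and 0.0464), with ranges of 0.0215 to 0.168 and 0.0312 to 0.170. Neuron genes, with 0 of 20 past the threshold and 5 higher at an unadjusted p under 0.05 (0 adjusted over the list alone), had an adjusted p = 0.00202 toward higher values, and an adjusted p = 0.643 with an estimated correlation. The count of 0 depended on 5 dpl replicate 1: without it 12 of 20 were higher at 28 than 14 dpl, as were 12 with only these time points fitted and 6 with array weights. It was 1 without 5 dpl replicate 2, with cyclic loess, the trend or either background filter, and 2 without 5 dpl replicate 3. No 5 dpl array enters a difference between 14 and 28 dpl. Leaving 1 out acts through the spread that the fit shares over all time points. Of the raw targets 677 were higher and 555 lower at 28 dpl, and of the authors' normalized probes 790 and 789. Here too the larger side turned: the raw table gave 268 higher and 360 lower when scaled to the 75th percentile, 789 and 806 with no background correction, 787 and 806 with normexp on the signals alone and 722 and 772 with definition 2 or 3 of a re-estimated background. The normalized probes numbered 776 and 788 without 5 dpl replicate 2, and 794 and 804 or 637 and 742 with those above the estimated background on at least 3 or on all 9 arrays. Leaving out 1 raw array of 28 dpl gave 447 and 308 or 420 and 268 for 2 of these arrays, and leaving out 1 of 14 dpl gave 374 and 294, 392 and 340, or 357 lower. The normalized probes numbered 442 and 394 without 14 dpl replicate 1, 494 and 519 without 14 dpl replicate 3, 509 and 448 without 28 dpl replicate 1, and 474 and 389 without 28 dpl replicate 3.

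**Figure D2:**
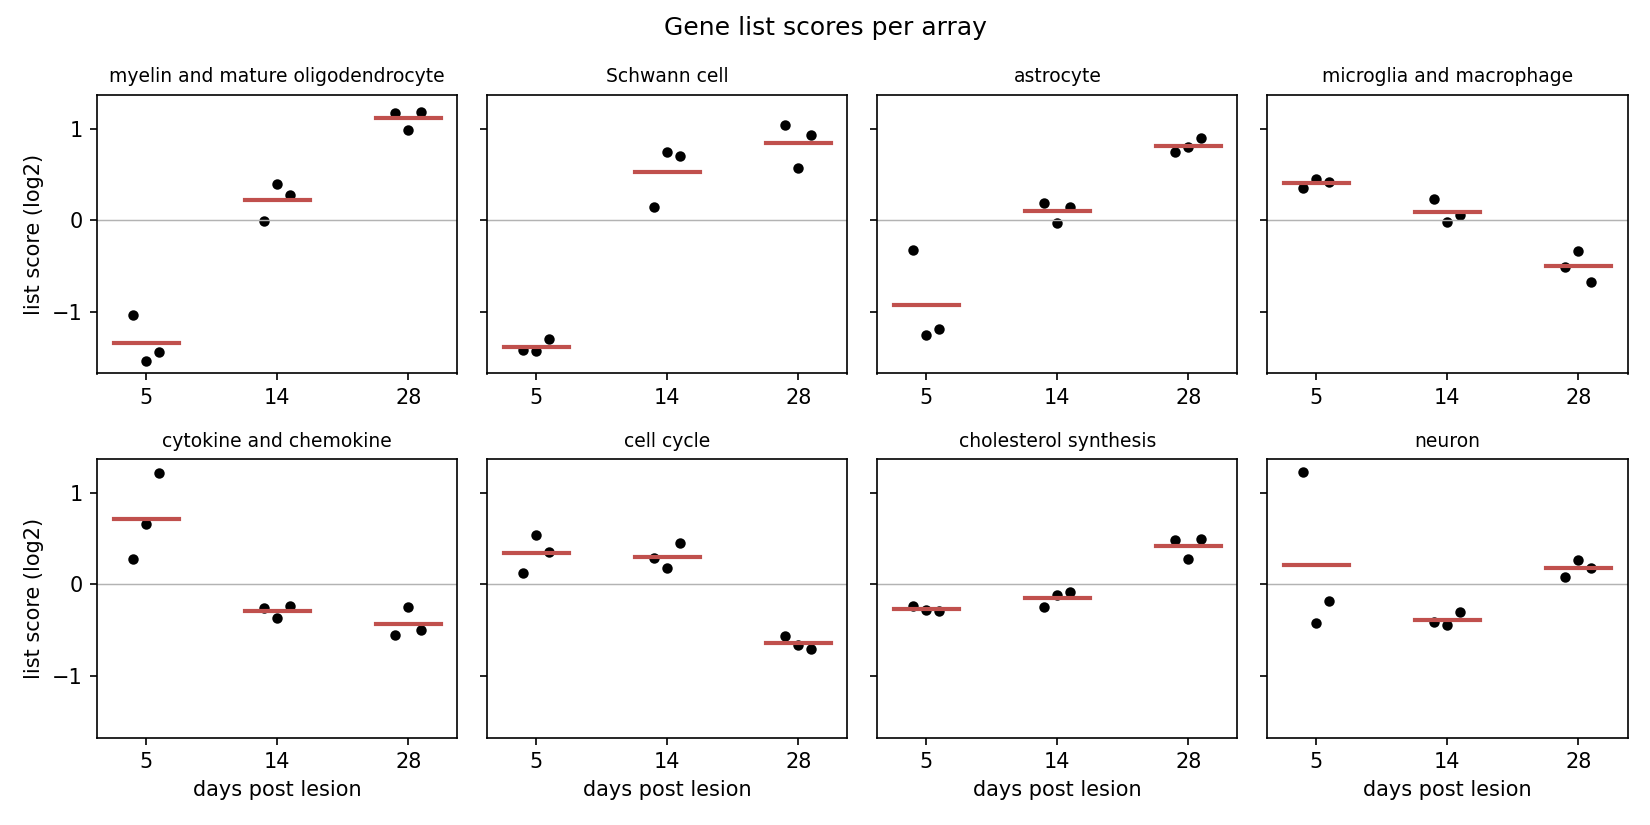
Each point is the score of a gene list on 1 array (the mean over its genes of the log2 value minus the gene's mean over all 9 arrays), by days post lesion, and red lines are group means. The neuron score of 5 dpl replicate 1, at 1.23, lies above all other arrays.

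Over the whole interval from 5 to 28 dpl, 23 of 24 myelin genes rose (23 adjusted over the list alone). Mal rose by 5.32 (SE 0.32) or 40-fold, Mog by 4.91 (SE 0.28) and Mobp by 4.88 (SE 0.20), and the list had an adjusted p = 1.2e-15, and an adjusted p = 0.313 with an estimated correlation. Astrocyte genes rose in 11 of 14 cases (13 adjusted over the list alone; Gfap by 2.90, SE 0.15), with an adjusted p = 7.69e-07, and an adjusted p = 0.371 with an estimated correlation. Schwann cell genes rose in 6 of 7 (6 adjusted over the list alone; Pmp22 by 3.47, SE 0.21), with an adjusted p = 5.49e-05, and an adjusted p = 0.313 with an estimated correlation. Rxrg rose by 2.88 (SE 0.24, adjusted p = 4.34e-05) and Rxrb by 0.48 (SE 0.07), whereas Rxra differed by -0.12 (SE 0.05, adjusted p = 0.0998). In the retinoid list 6 of 18 members rose and 1 fell (6 and 1 adjusted over the list alone), with an adjusted p = 0.077, and 0.0439 without 28 dpl replicate 3 and 0.0404 without 5 dpl replicate 1 (range 0.0404 to 0.5). Without 28 dpl replicate 2 or with array weights, 2 fell, and 3 of the 12 members above the estimated background on all 9 arrays rose.

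Of 22 microglia and macrophage genes 16 fell between 5 and 28 dpl (17 adjusted over the list alone), among them Adgre1 (a difference of -1.66, SE 0.10) and C1qc (-2.05, SE 0.22), with an adjusted p = 6.84e-06, and an adjusted p = 0.371 with an estimated correlation. Cytokine genes fell in 17 of 22 cases (17 adjusted over the list alone), with Cxcl13 down from 11.38 to 8.11, an adjusted p = 0.000117, and an adjusted p = 0.53 with an estimated correlation. Cell cycle genes fell in 24 of 25 (24 adjusted over the list alone; adjusted p = 1.37e-09, and adjusted p = 0.499 with an estimated correlation). Mmp7 fell by 4.42 (SE 0.39) and Selp, P-selectin, fell at least 6.48-fold to below the estimated background. Cholesterol synthesis genes rose in 13 of 16 cases and fell in 1 (13 and 2 adjusted over the list alone; adjusted p = 3.29e-05, and adjusted p = 0.329 with an estimated correlation). Neuron genes, with 0 of 20 past limma's threshold and 1 higher at an unadjusted p under 0.05 (0 adjusted over the list alone), had an adjusted p = 0.677, and 0.00123 toward higher values without 5 dpl replicate 1 (range 0.00123 to 0.916), when 11 of 20 were higher (1 with array weights). Of the raw targets 1921 were higher and 2205 lower at 28 dpl, and of the authors' normalized probes 2135 and 2542, but 2396 higher and 2294 lower after cyclic loess.

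**Figure D3:**
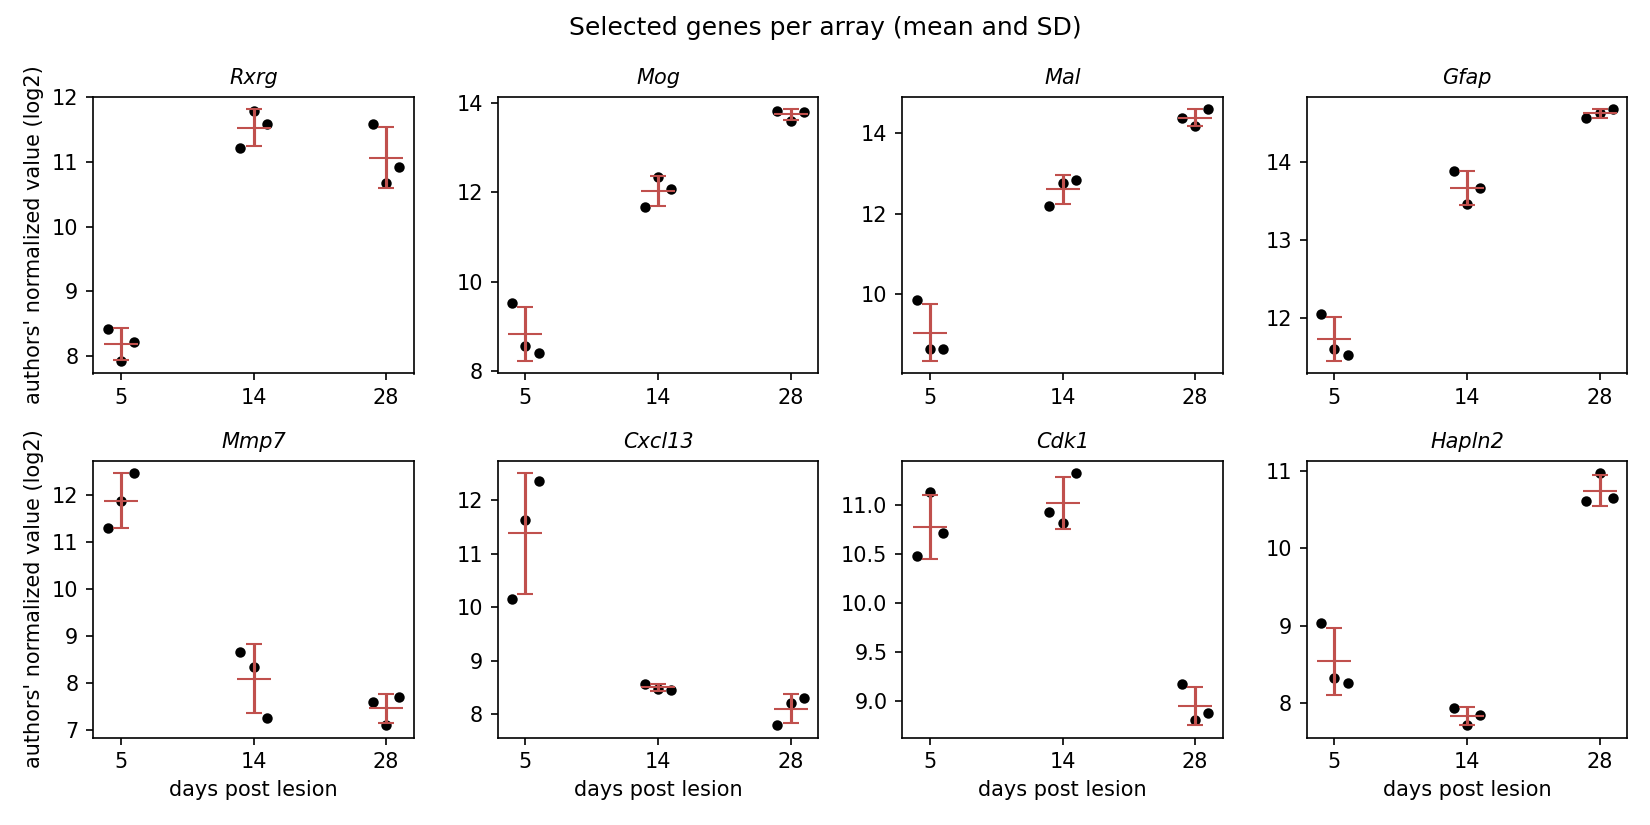
Points are the authors' normalized log2 values of 8 genes on each array by days post lesion, with the group mean and SD in red. Rxrg rises from a mean of 8.18 to 11.53 and then lies at 11.06.

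Some genes were highest or lowest at 14 dpl. Against the mean of 5 and 28 dpl, Entpd2, an ectonucleotidase, was higher by 1.83 (SE 0.24), Sod3, the extracellular superoxide dismutase, by 1.54 (SE 0.13) and Prc1, a mitotic spindle protein, by 1.28 (SE 0.14). Hapln2 differed by -1.81 (SE 0.17) and Pla2g7 by -1.37 (SE 0.17). The adjusted p of Entpd2 was 0.0103, and 0.0534 without 14 dpl replicate 2 (range 0.00250 to 0.0534). The genes named here were chosen with all 14 dpl arrays outside the range of the others. The contrast alone can also call genes that changed only between 5 and 14 dpl or only between 14 and 28 dpl. Counts from it are thus not counts of genes highest or lowest at 14 dpl. Of the raw targets 124 were higher and 122 lower, but 310 and 183 with a re-estimated background. With 1 raw array left out, 10, 31 or 59 were higher (14 dpl), 42, 62 or 78 (28 dpl) and 47 or 59 (5 dpl), and 5, 26 or 27 were lower (14 dpl), 42 or 72 (28 dpl) and 46 or 220 (5 dpl). Of the authors' normalized probes 236 were higher and 179 lower; 151 and 41, 42 and 18, and 76 and 62 without 14 dpl replicate 1, 2 and 3, 157 and 106 without 28 dpl replicate 3, 154 higher without 5 dpl replicate 3, and 323 lower without 5 dpl replicate 1.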

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

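The 3 background re-estimates and the settings on the authors' normalized table for cyclic loess and estimated background were chosen after the data had been seen. Pairwise counts of the raw table stayed within 1.5 times the reported ones except as follows, and where no reason is given the cause was not tested. Scaling to the 75th percentile gave 286 higher and 334 lower for 14 against 5 dpl, 268 and 360 for 28 against 14 dpl (42.7% of the called targets higher, against 54.95% as reported), 1167 and 1338 for 28 against 5 dpl, 27 and 16 for 14 dpl against the others and 2070 for any difference. Array weights gave 1290 lower at 14 than 5 dpl and 838 lower at 28 than 14 dpl, and no filter gave 332 for the latter, with more targets tested. For 14 dpl against the others, where 124 higher and 122 lower were reported, no background correction gave 290 and 197, normexp on the signals alone 298 and 198, no filter 24 and 34, the trend with robust fitting 193 and 203 and array weights 280 and 336. There definitions 2 and 3 of the re-estimate both gave 310 higher, definition 1 gave 141, and 236 came from the authors' normalized values. The re-estimates raised the count for 14 against 5 dpl from 799 higher and 835 lower to 867 and 873 with definition 1, and to 1164 and 993 with definitions 2 and 3.

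Leaving out 1 array, which also leaves fewer samples, gave these ranges in the raw table: 342 to 807 higher and 360 to 1074 lower for 14 against 5 dpl, 374 to 836 and 268 to 649 for 28 against 14 dpl, 1505 to 1941 and 1637 to 2296 for 28 against 5 dpl, 10 to 131 and 5 to 220 for 14 dpl against the others, and 2644 to 3783 for any difference. In the authors' normalized table they were 668 to 1227 and 617 to 1352, 442 to 1082 and 389 to 968, 1800 to 2248 and 2042 to 2681, 42 to 290 and 18 to 323, and 3495 to 4650.

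In the authors' normalized table array weights gave 490 higher and 428 lower for 14 dpl against the others. The replicate numbers do not pair the samples: 1 of 9 same-numbered pairs had a correlation of deviations over 0.1, with a range from -0.29 to 0.15. With the replicate block, 500 probes were lower at 28 than 14 dpl, and 97 higher and 102 lower at 14 dpl against the others; 888 and 856 were called for 14 against 5 dpl. The block was run on that table alone, since the raw columns carry no replicate numbers. Of 69 list tests 29 passed with the preset correlation and 0 of these with an estimated correlation. Gene names tie all gene and list results to the authors' normalized table, so alternatives of background correction, the 75th percentile and detection were not run for them, nor was the slide block for any result. No named gene past the threshold changed its direction under the alternatives run, and of 245 gene calls 19 were lost with the block (among them Mcm6 and Mcm2 from 5 to 14 dpl, adjusted p of 0.0689 and 0.0539, and Il1a from 14 to 28 dpl, 0.0956), 3 with cyclic loess and 1 with the trend. With only the time points compared, which the contrast of 14 dpl with the others does not allow, 229 calls held and 6 were lost. With the block the retinoid list passed from 14 to 28 dpl (camera, adjusted p = 0.0488), while its members that rose went from 4 to 1. Leaving out 1 array at a time kept 2063 calls and lost 142. Background limits the dim genes, whose differences are understated on that table if the slope given above holds.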

Other observations

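All tests of explanations and of other splits in this part were chosen or written down after the results had been seen. Complement genes parted: of 12 measured, 6 rose and 6 fell from 5 to 28 dpl (6 and 6 adjusted over the list alone). Serping1, the C1 inhibitor, rose by 1.89 (SE 0.23), Cd59b, a membrane inhibitor of complement, by 1.36 (SE 0.10) and C4b by 1.42 (SE 0.16), while C1qc differed by -2.05 (SE 0.22). The list's test gave an adjusted p = 0.79 upward, while its median lay below 0 and its mean difference was -0.03. C1qa, C1qb and C1qc were written into both this list and that of microglia and macrophages. The fall of C1qc therefore counts in both. Growth factor genes rose in 10 of 13 cases and fell in 1 over the same interval (11 and 1 adjusted over the list alone), with Ptn, pleiotrophin, up by 2.69 (SE 0.15), Cntf by 2.04 (SE 0.10) and Igfbp2 by 3.81 (SE 0.29). Without 14 dpl replicate 1, 2 fell, and without 28 dpl replicate 1, 0 did. Its adjusted p was 0.000197, and the adjusted p = 0.259 with an estimated correlation. Of 13 T, B and natural killer cell genes 10 fell (12 adjusted over the list alone; 6 without 28 dpl replicate 3), including Cd8a (a difference of -2.12, SE 0.36), with an adjusted p = 0.0024, and an adjusted p = 0.58 with an estimated correlation. Genes of the endothelial cell and pericyte list fell in 6 of 9 cases (6 adjusted over the list alone). The list had an adjusted p = 0.0207, and an adjusted p = 0.316 with an estimated correlation.

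From 5 to 28 dpl, lysosome and lipid handling genes fell in 12 of 23 cases and rose in 1 (13 and 1 adjusted over the list alone), with a difference of -3.16 (SE 0.18) for Cd36 and an adjusted p = 0.00568, and an adjusted p = 0.5 with an estimated correlation. Matrix genes rose in 7 of 21 and fell in 3, interferon and antigen presentation genes fell in 8 of 21 and rose in 1, Wnt, Notch and BMP genes rose in 6 of 17 and fell in 2, reactive glia genes rose in 5 of 12 and fell in 3, and immediate early genes rose in 4 of 12 and fell in 3. Mitochondrial genes fell in 6 of 24 and rose in 1, 1 of 5 blood genes fell (S100a8), and 1 of 5 choroid plexus and ependyma genes rose (Tekt1). Without 5 dpl replicate 2, 4 of the 5 blood genes fell, and without 28 dpl replicate 3, 5 interferon genes did. Those that fell numbered 1 for Wnt genes without 5 dpl replicate 1 or 3 or 28 dpl replicate 3, and 1 for immediate early genes without 5 dpl replicate 3 or 28 dpl replicate 1 or 3. The single lysosome gene that rose did not without 5 dpl replicate 2 or 3 or 28 dpl replicate 2, and the single mitochondrial gene did not without 5 dpl replicate 2 or 3 or 28 dpl replicate 1 or 3. The single interferon gene that rose did so only with 14 dpl replicate 2, 28 dpl replicates 1 and 3 and all 5 dpl arrays kept. The lists from matrix genes onward did not pass, with adjusted p-values of 0.356, 0.0992, 0.085, 0.351, 0.529, 0.0958, 0.126 and 0.335 in that order. Of these, interferon genes passed without 28 dpl replicate 1 (0.0213) or 5 dpl replicate 1 (0.0456), mitochondrial genes without 5 dpl replicate 3 (0.0217) and blood genes without 5 dpl replicate 2 (0.0213). Their ranges over the alternatives were 0.0213 to 0.695, 0.0217 to 0.584 and 0.0213 to 0.53. Adjusted over the list alone, 7 matrix genes rose and 3 fell, 2 and 9 interferon genes, 6 and 2 Wnt genes, 6 and 3 reactive glia genes, 4 and 3 immediate early genes and 1 and 6 mitochondrial genes, while 1 blood gene fell and 1 choroid plexus gene rose.

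From 5 to 14 dpl, growth factor genes rose in 8 of 13 cases (8 adjusted over the list alone, where 1 fell; 4 without 5 dpl replicate 2 or 3 or 14 dpl replicate 2, and 5 without 14 dpl replicate 3), with an adjusted p = 4.87e-05, and an adjusted p = 0.259 with an estimated correlation. T, B and natural killer cell genes fell in 5 of 13 (11 adjusted over the list alone; adjusted p = 0.000293, and adjusted p = 0.53 with an estimated correlation). They numbered 11 without 5 dpl replicate 1 or with array weights, 2 without 14 dpl replicate 2, and 3 without 5 dpl replicate 2 or 14 dpl replicate 3. Lysosome genes fell in 7 of 23 and rose in 2 (8 and 2 adjusted over the list alone; adjusted p = 0.021, and adjusted p = 0.53 with an estimated correlation). Those that rose numbered 0 without 5 dpl replicate 3 or 14 dpl replicate 1 or 2, and 1 without 5 dpl replicate 2, 14 dpl replicate 3 or 28 dpl replicate 1 or 3. Wnt, Notch and BMP genes rose in 5 of 17 (5 adjusted over the list alone; 3 without 5 dpl replicate 2, when 1 fell, or 14 dpl replicate 3), with Dkk3 up by 1.33 (SE 0.14) and an adjusted p = 0.0473, and an adjusted p = 0.5 with an estimated correlation; that list did not pass without 14 dpl replicate 2 (0.0677), 14 dpl replicate 3 (0.0802), 28 dpl replicate 2 (0.0551) or 5 dpl replicate 2 (0.101), nor with cyclic loess (0.0557) or only probes above the estimated background on at least 3 arrays (0.0592) or on all 9 (0.0668), with a range of 0.0157 to 0.5. From 14 to 28 dpl, growth factor genes rose in 2 of 13 (3 adjusted over the list alone; adjusted p = 0.0363, and adjusted p = 0.36 with an estimated correlation), which became 0.0818 without 14 dpl replicate 1, 0.101 without 28 dpl replicate 2 and 0.0524 with cyclic loess (range 0.0146 to 0.36). Lysosome genes fell in 5 of 23 (9 adjusted over the list alone, where 2 rose; 3 without 14 dpl replicate 1; 1 rose without 14 dpl replicate 2 or 5 dpl replicate 1; adjusted p = 0.0248, and adjusted p = 0.535 with an estimated correlation), which became 0.0808 without 28 dpl replicate 1, 0.0670 without its replicate 3 and 0.0654 with cyclic loess (range 0.00184 to 0.535). Median and mean differed in sign, with an upward test, for complement (-0.09 and 0.03 from 5 to 14 dpl, 0.09 and -0.06 from 14 to 28 dpl), choroid plexus genes from 14 to 28 dpl (0.02 and -0.18) and neuron genes from 5 to 28 dpl (0.06 and -0.04). With a downward test they did so for reactive glia (0.02 and -0.06) and immediate early genes (-0.02 and 0.01) from 5 to 14 dpl.

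The 6 arrays of a pairwise comparison have 10 splits, the real one included, too few for a share under 0.05. The raw table gave 1634, 1232 and 4126 called targets for 14 against 5, 28 against 14 and 28 against 5 dpl, where the highest of the other splits gave 1, 0 and 0, and the real split was the 1 split with as many. The authors' normalized table gave 2193, 1579 and 4677 against 0, 0 and 0. For any difference 1 of 100 splits, the real one, reached 3648 targets (highest other 1516), and 1 of 100 reached 4365 probes (highest other 1939). Chance is thus unlikely there, provided that the arrays are independent samples. The splits cannot tell time point from processing, if the arrays of a time point were processed together. Whether they were is not given in the sources used here. For 14 dpl against the others, 2 of 100 splits reached 246 targets and 5 of 100 reached 415 probes, the real one included. These shares are no measure of chance, because most of the other splits that reached the count hold a real difference between time points. The one with 1398 targets set the 3 arrays of 28 dpl against the rest; those with 4085 and 2994 probes set apart the 3 arrays of 5 dpl, that with 2049 the 3 of 28 dpl, and that with 1748 set apart 2 arrays of 5 dpl with 1 of 14 dpl. The list tests with the preset correlation are not set apart by the real split: 10, 8 and 11 lists were called with it, adjusted within each contrast, and other splits called up to 14, 12 and 12, with 4, 6 and 4 of the 10 splits calling as many. But each of the other splits mixes arrays of the time points compared and can keep part of their difference. The splits therefore cannot decide how far the list p-values can be trusted. With an estimated correlation 0 of the 29 list tests that passed did so, so the p-values with the preset correlation hang on that setting.

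The fall of macrophage genes beside the rise of myelin and astrocyte genes could come from a lower share of macrophages. That alone would raise the other cell types alike. Instead the astrocyte list had a mean change of 1.73 from 5 to 28 dpl and the endothelial and pericyte list of -0.67. The difference of their scores changed by 2.40 (SE 0.31), but it restates these list changes and is no separate test. Endothelial and pericyte genes may also have changed for reasons of their own. How much a lower share of macrophages added to the rise of the myelin and astrocyte lists was therefore not settled. A normalization between arrays moves probes of 1 level alike. Beyond the median change of the 200 probes nearest in level, the myelin list changed by a median of 2.39 (quartiles 1.37 and 3.52). The astrocyte list changed by 1.77 (0.47 and 2.89) and the macrophage list by -0.84 (-1.25 and -0.23). These are nearly the lists' own medians of 2.32, 1.72 and -0.87, because quantile normalization holds the median change of all probes near 0 (-0.03). The values show that the lists moved apart from probes of their level. They cannot tell whether the normalization removed a shift of all probes. A change in the number of oligodendrocytes or astrocytes, or in expression per cell, stays open and was not tested. How much neighbouring tissue each sample held stays open too and was not tested. Neuron scores were 1.23, -0.42 and -0.18 at 5 dpl, -0.41, -0.44 and -0.30 at 14 dpl and 0.09, 0.26 and 0.18 at 28 dpl.

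Neuron genes were high on the array of 5 dpl replicate 1. Of 20 members 19 were higher on it than on each of the other arrays, which is consistent with neighbouring tissue with neurons in that sample, a hypothesis found and tested on the same data. Gap43 was at 12.18 there, Snap25 at 11.75 and Calb1 at 11.55 (signals of different probes do not rank abundance), against at most 11.87, 9.67 and 9.62 elsewhere, and 13 of the 20 lay above the estimated background on all 14 and 28 dpl arrays. That the array belongs to 14 or 28 dpl is argued against by the myelin list, whose score on it minus the lowest of those arrays was -1.03 (SD over the 5 dpl arrays 0.26).

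Rxrg rose by 14 dpl and did not rise further, while the myelin list still did. Bright signals that no longer rise are argued against as the cause, since 6 of the 9 myelin genes brighter than Rxrg at 14 dpl rose by 28 dpl. From 14 to 28 dpl the myelin score minus Rxrg changed by 1.36 (SE 0.24) and the Schwann score minus Rxrg by 0.78 (SE 0.18), but these differences restate the pattern they were found from, so whether Rxrg changed along with either list stays open. Which cells carry Rxrg may differ between the time points and was not tested.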
